A study of Mus musculus with 10 samples.

How the data were processed

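Gene expression was measured by RNA sequencing in 4 libraries of mouse hair follicle stem cells (HFSCs), and SOX9 binding by chromatin immunoprecipitation and sequencing (ChIP-seq) in 3 libraries, 2 of HFSCs and 1 of interfollicular epidermal (IFE) cells. Per the labels' protocols, cells were sorted from telogen back skin, RNA libraries were made with the Illumina TruSeq RNA kit, and ChIP libraries from sonicated nuclei with an Illumina DNA kit. The 3 input DNA libraries had no values used here.

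Expression values were deposited as FPKM (fragment counts scaled by transcript length and by mapped fragments of the library), per the file headers, in 1 table of 37298 gene rows with a column for each RNA library. The submitters' processing notes name Bowtie, TopHat, TopHat2, Cufflinks 1.0.3 and the mouse genome build mm9, without saying which tool made which values. Any further scaling, filtering or strand setting is not given in the sources used here. SOX9 peaks were deposited as 1 list per ChIP library, each with only a chromosome, a start and an end; the peak caller, its threshold and its use of the input libraries are not given in the sources used here. The lists hold no height, score or p-value, so that peak strength could not be compared. HFSC list 1 and the IFE list each hold a peak on the mitochondrial chromosome with a start below 0, and these peaks were kept in the counts.

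FPKM depends on gene length and on the total of each library, so a few abundant transcripts lower all others, and gene-length differences between library preparations shift short genes against long ones. The number of reads per library is not given, and the low FPKM values shared no common step between libraries (at most 3.46% of gene ratios fell in 1 bin), so the depth behind each value is unknown and no count model or counting interval was used for expression. With the depth unknown, an exact 0 does not show absence, and genes at 0 are described only as listed at 0.

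Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) over the 14455 genes with a mean FPKM of at least 1 over the 4 libraries. A fold change is on this log2(FPKM + 1) scale, which understates the change of low genes. Each SE is limma's moderated standard error, which shares spread across genes and is not the spread between the pairs of that gene. The blocked fit leaves 1 residual degree of freedom per gene. Both the fit with genotype alone and the fit with the replicate number as a block were set before the data were examined, as were the gene lists, the windows around gene loci and the rule for naming genes. The replicate numbers pair the libraries: per the labels, both replicate 1 libraries come from males of day 75 treated with RU486 on days 48 to 61, and both replicate 2 libraries from females of day 80 treated on days 53 to 66. Deviations from the group means of same-numbered libraries correlated at 0.812 across genes, a correlation across genes that are not independent replicates. The labels do not say whether a library came from 1 mouse or from several, so p-values measure the spread between these 4 libraries only.

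Gene lists, 20 in number, were tested with limma's camera at the preset inter-gene correlation 0.01, and 18 of them had the minimum of 5 tested members. Camera with an estimated correlation and fry were run as alternatives. The former rests on the residual degrees of freedom, 2 without and 1 with the block, which leave it little power. Fry tests a list against no change, not against other genes. Symbols and Ensembl identifiers are those of the deposited table, and gene positions are its locus coordinates, which give no strand, exon or transcription start and which neighbouring genes can share. Y-linked genes stood between 5.59 and 55.4 FPKM in the replicate 1 libraries and at 0.00363 or less in replicate 2, and Xist above 60 FPKM only in replicate 2, as the sexes in the labels require.

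Peaks of different lists were called shared when they overlapped by at least 1 bp, and chance overlap was taken from 1000 circular shifts within chromosomes. A gene was counted as having a peak when a peak in both HFSC lists lay within 10 kb of its locus. Called genes were compared with the other tested genes by Fisher's exact test, and with 10000 draws of genes matched on locus length and mean FPKM (5 bins of each). The top bin of mean FPKM has no upper bound, so the draws may not match the most abundant genes. Shares of peaks and genes carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

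A fixed rule chose genes to name, starting with Sox9. It took the 12 genes with the highest and the 12 with the lowest change among those past the threshold. Where fewer passed, places up to 6 went to the smallest p. It also took up to 4 members of each list by smallest p, and called genes with a peak. A set of 16 fixed genes of HFSC identity, niche signals and epidermal lineages was added. Genes outside the rule are named as well, such as the remaining calls, members past the test over a list alone, and some genes 2-fold in both pairs. As the fit without the block called no gene, the same rule was applied to the calls of the blocked fit, a choice made after the result was seen. The test of peaks by called genes was moved to these calls in the same way. The widest peaks took the place of the highest scoring ones, since the lists hold no score.

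Each step was tested on simulated data. The 14455 simulated genes had independent normal noise, with 1 spread for all genes of like mean, taken from these libraries. The fit without the block recovered 0 of 100 genes seeded at 2-fold and 0 of 100 at 4-fold, and the blocked fit recovered 91 and 100 of them with 6 false calls in all. Camera with the block gave p under 0.05 for 8 of 100 random lists. Differences in spread between genes of like mean, and correlation between genes, were not simulated. These rates therefore need not hold for the real data. Of 500 shared peaks planted in simulated lists of 3000, the overlap count found 582 with 108.5 from chance. Alternatives covered the pseudocount, the filter on low values, the scaling, the block, the trend, the threshold, leaving out each library, the overlap that counts as shared, and the distance to a gene. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the peak comparisons and plots.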

Results

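Hair follicle stem cells (HFSCs) of the bulge, the resting stem cells that renew the hair, were studied together with basal cells of the interfollicular epidermis (IFE), the skin surface between follicles. The subject was SOX9, a transcription factor of the HMG-box family that HFSCs express, and the question was which genes depend on it and where it binds, with secreted signals of the stem cell niche as the stated interest. Expression was measured in HFSCs sorted as integrin α6-high, CD34-positive, YFP-positive cells from back skin in telogen, the resting phase of the hair cycle. Of the 4 RNA libraries, 2 are labelled Sox9 conditional knockout (cKO) and 2 control; the control titles call the animals heterozygous and their genotype field calls them wild type. Deletion used a Cre recombinase fused to a progesterone receptor, which RU486 activates. Per the labels, replicate 1 of each genotype is male at day 75 and replicate 2 female at day 80. SOX9 binding was measured by ChIP-seq in 2 HFSC libraries and 1 IFE library from untreated CD-1 females of days 52 to 60, the IFE cells being sorted as integrin α6-high and CD34-negative.

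The FPKM values of the 37298 listed genes summed to 584125 in the replicate 1 library labelled cKO, 555420 in its control, 903766 in the replicate 2 library labelled cKO and 786914 in its control. The 100 most abundant genes held between 25.3% and 31.5% of these sums. Keratins of basal cells and of the bulge were abundant in all 4 libraries: Krt5 lay between 6277 and 8536 FPKM, Krt14 between 1620 and 2706, and Krt15, a bulge keratin, between 8703 and 10894. Log2 values correlated across genes at 0.982 and 0.976 within the 2 same-numbered pairs, and at only 0.916 and 0.913 between replicates of one genotype. The HFSC peak lists hold 8181 and 2989 peaks with median widths of 616 and 646 bp, and the IFE list holds 5209 with a median of 522 bp. Each genotype has 2 libraries, which is the n behind every expression value given here.

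The level of Sox9 was examined first, as a check of the genotype labels. Sox9 (ENSMUSG00000000567; mm9 chromosome 11, 112643537 to 112649074) stood at 71.3 FPKM in the replicate 1 library labelled cKO against 82.7 in its control, and at 80.5 in the replicate 2 library labelled cKO against 46.5 in its control. The log2 differences of -0.21 and 0.78 point in opposite directions, and their mean of 0.28 ± 0.22 (moderated SE) was not past the threshold (limma with the replicate block, adjusted p = 0.690). This SE shares spread across genes and understates how far the 2 pairs lie apart. Sox9 FPKM was thus not consistently lower in the libraries labelled cKO. The FPKM covers the whole gene, and no value for the deleted part was used here. With no block, the mean was -0.13 without the replicate 2 control and 0.69 without the replicate 1 control. Both values also carry part of the difference between replicates. Directions given here therefore follow the labels, and these libraries are called "labelled cKO" throughout.

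Next to Sox9, a locus of higher coordinates was listed in both libraries labelled cKO and in neither control. Gm11681, a predicted gene that begins 4970 bp beyond the Sox9 locus (112654044 to 112660322), stood at 4.82 and 1.55 FPKM in the libraries labelled cKO and is listed at 0 in both controls. A further locus at 112686467 to 112693783, 4933434M16Rik, stood at 0.734 and 0.889 FPKM in the libraries labelled cKO, at 0.0205 in the replicate 1 control and at 0 in the replicate 2 control; it was singled out after its values were seen. BC006965, whose locus ends 247 bp below Sox9, stood at 1.39 and 1.95 FPKM in the libraries labelled cKO and at 1.41 and 2.60 in the controls. Gm11681 did not pass the test over all genes (log2 change 1.95, limma with the replicate block, adjusted p = 0.116), and 4933434M16Rik lay below the filter on mean FPKM. Within the Sox9 locus itself, HFSC list 1 has a SOX9 peak at 112646839 to 112647463, HFSC list 2 has peaks at 112643675 to 112644425 and at 112645931 to 112646597, and the IFE list has one at 112647001 to 112647381. The HFSC peaks here do not overlap one another, so none counts as shared.

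**Figure D1:**
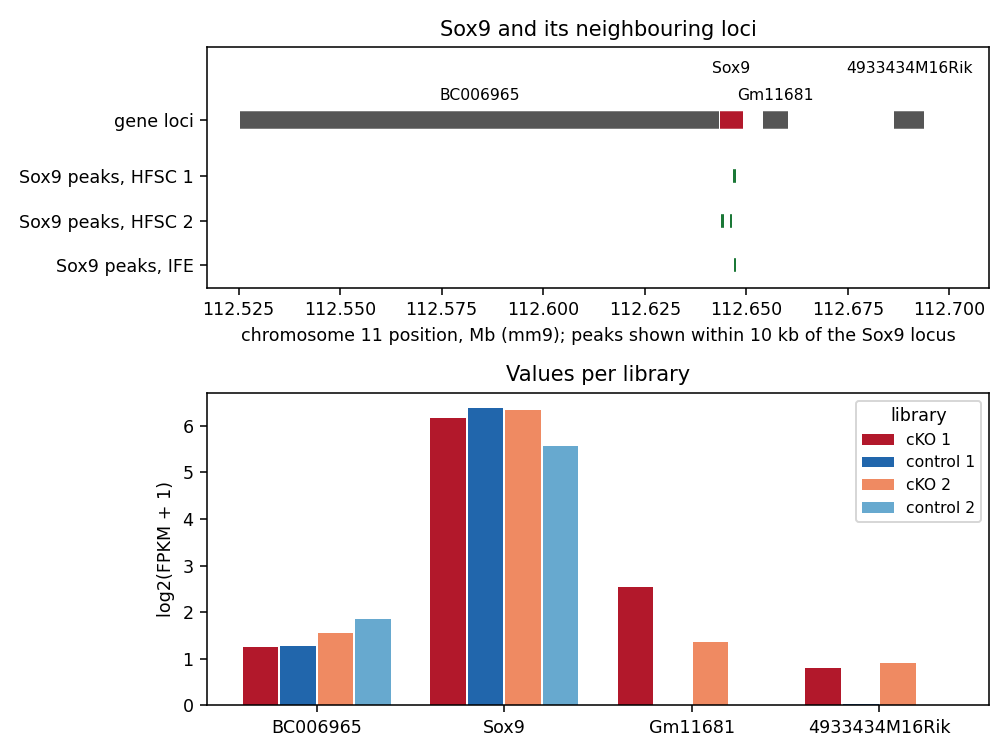
The upper panel maps the Sox9 locus, its neighbouring loci and the SOX9 peaks of the 3 lists on chromosome 11 (mm9, Mb); the lower panel gives log2(FPKM + 1) of each gene, with a bar per library. Gm11681 and 4933434M16Rik have bars in the 2 libraries labelled cKO and values at or near 0 in the controls, while the Sox9 bars do not separate the genotypes.

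The comparison of libraries labelled cKO with controls asked which genes change when Sox9 is deleted in HFSCs. Among genes higher in the libraries labelled cKO were Stfa3, a stefin that inhibits cysteine proteases (7.18 to 44.0 FPKM in replicate 1 and 16.9 to 138 in replicate 2), and Myoc, which encodes the secreted glycoprotein myocilin (35.7 to 134 and 64.2 to 225 FPKM). Among genes lower in them were Lhx2, a LIM-homeodomain factor that maintains HFSCs (359 to 114 and 195 to 87.1 FPKM), Grik1, a glutamate receptor subunit, and Fzd9, a WNT receptor. With genotype as the only term limma called 0 of 14455 genes (93 had p under 0.05 before adjustment, and the smallest adjusted p was 1.00). Without the block the smallest p belonged to Ptger4, Thbd, Gm11681, Stfa3 and the small RNAs Snora70 (1.49) and Mir678 (1.34) on the higher side, and to Snord4a, Grik1, D0H4S114, Fzd9, Snord72 and St6galnac2 on the lower side, none of them past the threshold. With the replicate number as a block, which takes out the difference between the male and female pairs, limma called 41 genes at an adjusted p under 0.05, 15 higher and 26 lower, and 1648 had p under 0.05 before adjustment. Flipping the genotype labels of one pair in the blocked fit left 0 calls and 321 genes with p under 0.05.

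Genes higher in the libraries labelled cKO included receptors, feedback regulators and matrix proteins. Stfa3 had a log2 change of 2.71 ± 0.16 (SE; limma with the replicate block, adjusted p = 0.00738) and Myoc one of 1.84 ± 0.12 (adjusted p = 0.00738). Thbd (thrombomodulin, a receptor that restrains blood clotting) was higher by 1.62 ± 0.20 (adjusted p = 0.0347), and Ptger4 (the EP4 receptor for prostaglandin E2) by 1.502 ± 0.17 (adjusted p = 0.0304). Ramp1, a subunit of the receptor for calcitonin gene-related peptide, was higher by 1.47. The feedback inhibitors of receptor tyrosine kinase signalling Errfi1 and Dusp6 were higher by 1.41 and 1.24, the matrix protease Adamts1 by 1.42 and the matricellular protein Thbs2 by 1.24. Slit3, a secreted guidance cue, was higher by 1.35 ± 0.16 (adjusted p = 0.0347), and Fgfbp1, a carrier of fibroblast growth factors, by 1.17. Ccl27a, a chemokine of keratinocytes that attracts T cells, was higher by 1.39, with Ccl27b, Gm2506 and Gm13306 close behind at 1.204 to 1.219; these are near-identical copies whose reads the counting can split, so that they are uncertain and stand for 1 gene family.

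Genes lower in the libraries labelled cKO included a regulator of HFSCs and several secreted or matrix proteins. Lhx2 gave -1.65 and -1.16 in the 2 pairs (mean log2 change -1.40 ± 0.15, limma with the replicate block, adjusted p = 0.0273). Grik1 changed by -2.64 ± 0.23 (adjusted p = 0.0164), Fzd9 by -2.23 ± 0.22 (adjusted p = 0.0252), and the sialyltransferase gene St6galnac2 by -2.19 ± 0.18 (adjusted p = 0.0164). D0H4S114 changed by -2.15 ± 0.15 (adjusted p = 0.00738), and S100a4, a small calcium-binding protein, by -1.68 from control levels of 1168 and 2862 FPKM. Sostdc1, a secreted antagonist of BMP and WNT signals, changed by -1.09 and Timp2, an inhibitor of matrix metalloproteases, by -0.98. The matrix protease Mmp11, the heparan sulfate sulfatase Sulf2, the ubiquitin ligase Wwp2, the peptide hormone gene Cck, Noxo1, Wfdc3, Gm16314, Paqr6, Serpinb11, Fam132a, Thsd1, Phyhip and 2310057J16Rik made up the other calls of protein-coding or long transcripts, between -1.66 and -1.04. The remaining 5 calls, Snord4a, Snord72, Snord45b, snoU13 and Mir23a, are small RNAs that this library type captures poorly, and are uncertain.

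All 41 called genes kept their sign in the 11 other blocked fits with unflipped labels in which they were tested. Over these fits the change of Lhx2 lay between -1.58 and -1.37 and that of D0H4S114 between -2.23 and -1.89. Other changes moved further: Grik1 lay between -3.61 and -1.35, Fzd9 between -2.69 and -1.34, and Thbd between 0.97 and 1.94. Removing a trend on locus span ended every call (smallest adjusted p = 0.0508 with limma), as did dropping the mean trend or the filter on low values, and quantile normalization kept 3. Leaving out 1 library leaves the blocked fit no residual degrees of freedom; the fit without the block then called 41 genes without the replicate 1 library labelled cKO, 4 without its control, 7 without the replicate 2 library labelled cKO and 2 without its control. With 1 library left out and no block, part of the difference between replicates enters every change. A moved or turned value, of a gene or of a list, therefore does not show that the genotype difference rests on 1 library. This holds for all values given here with 1 library left out. Without the replicate 1 library labelled cKO the changes were 0.49 for Adamts1, 0.79 for Dusp6, 0.72 for Thbs2, 0.70 for Slit3, -0.80 for S100a4 and -2.73 for snoU13, while without the replicate 2 control they were 0.70, 0.82, 0.91, 0.56, -1.03 and -2.64. Without the replicate 1 control they were 2.14 for Adamts1, 2.14 for Slit3, -2.32 for S100a4, 0.88 for Ccl27b, -1.03 for Mir23a and -0.67 for snoU13, and without the replicate 2 library labelled cKO 2.35, 1.99, -2.56, 0.69, -1.39 and -0.58, with Ccl27a at 0.85. Fgfbp1 stood at 1.85 without the replicate 1 library labelled cKO and 0.49 without the replicate 2 library labelled cKO, Paqr6 at -0.68 and -2.14, Fam132a at -0.74 and -1.79, Gm2506 at 1.73 and 0.68 and Gm13306 at 1.75 and 0.68. Paqr6 was also at -2.24 without the replicate 1 control and -0.58 without the replicate 2 control, and Fgfbp1 at 0.70 without the replicate 1 control.

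**Figure D2:**
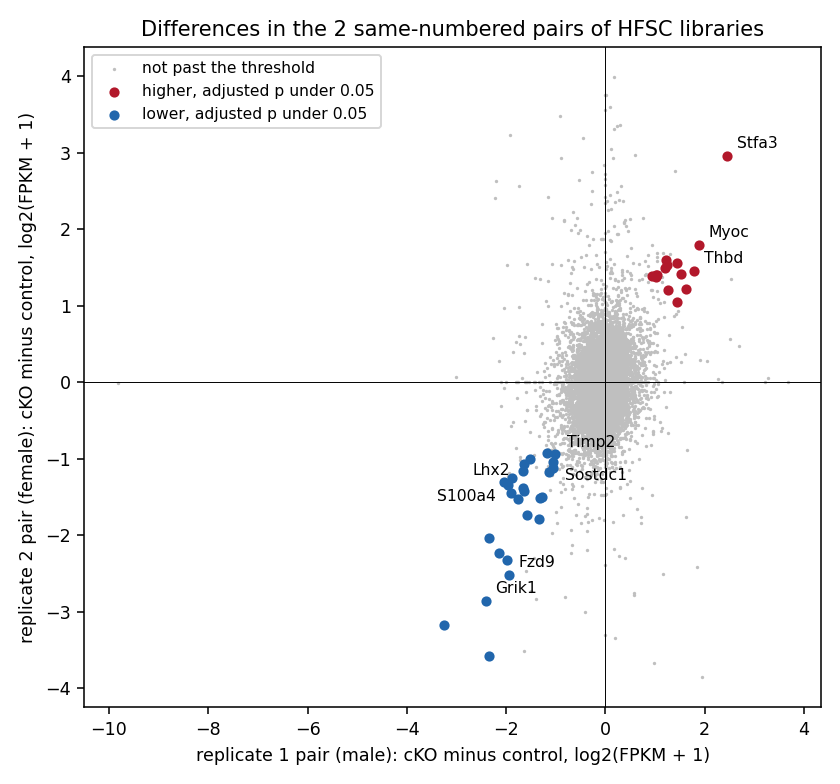
Each point is one of 14455 genes, placed by its difference between the library labelled cKO and the control, in log2(FPKM + 1), in the male pair (horizontal axis) and the female pair (vertical axis). The 41 genes called by limma with the replicate block are coloured, 15 higher in red and 26 lower in blue, and all lie on the same side of 0 in both pairs.

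Markers of HFSCs and epidermal lineages that had been fixed by name mostly stayed short of the threshold. Apart from Lhx2, the mean log2 changes were -0.58 for Nfatc1, a factor that keeps HFSCs quiescent, -0.28 for Tcf7l1, a WNT-pathway repressor of the bulge, -0.53 for Cd34, -0.26 for Lgr5 and 0.04 for Krt15, with adjusted p between 0.247 and 0.967 (limma with the replicate block). Inhbb, which encodes an activin subunit, gave -0.95 (adjusted p = 0.169; -1.43 without the replicate 2 control and -0.47 without the replicate 1 control), and Tgfb2, a TGF-beta ligand, 0.41 (adjusted p = 0.666). Inhba, the other activin subunit gene, lay below the filter at 0, 0.133, 0.822 and 0.0129 FPKM in the order cKO 1, control 1, cKO 2 and control 2. The epidermal differentiation genes Krt1, Krt10 and Ivl gave -0.27, -0.30 and -0.47, the sebocyte gene Scd1 0.17, the basal keratins Krt5 and Krt14 0.22 and -0.07, and the proliferation marker Mki67 0.01; the sign for Krt5 flipped to -0.04 with quantile normalization. Among other members of the SOX family, Sox4 (ENSMUSG00000076431) gave 0.86 (adjusted p = 0.270).

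Genes changed at least 2-fold in the same direction in both same-numbered pairs were counted as a check that needs no model of the spread. There were 28 such genes higher and 40 lower in the libraries labelled cKO, among them Stfa3, Myoc, Thbd and Slit3 on one side and Lhx2, Grik1, Fzd9 and Sostdc1 on the other. If the pairs were independent and every gene equally likely to pass, 1.32 higher and 2.24 lower would be expected, from 80 higher and 162 lower in the male pair and 239 higher and 200 lower in the female pair. Genes do not all vary alike, and a variable gene can pass in both pairs by chance. These expected numbers are therefore too low a measure of chance. Opposite 2-fold changes were seen for 18 genes. Pairing each library labelled cKO with the control of the other replicate gave 46 genes in a common direction and 1614 in opposite directions, since the replicates themselves differ: 1180 genes were at least 2-fold higher and 779 at least 2-fold lower in replicate 2 than in replicate 1 in both genotypes. The differences of the 2 pairs correlated at 0.217 across genes, which are not independent replicates. On log2(FPKM + 0.1) 135 genes passed, and on log2(FPKM + 5) 24.

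Gene lists fixed in advance were then compared with all other tested genes. WNT signalling genes, most of them receptors, antagonists and feedback genes, were lower as a group in the libraries labelled cKO by camera at its preset correlation (adjusted p = 0.000364 without the block and 0.00136 with it), but not with an estimated correlation (adjusted p = 0.824 and 0.811). That alternative has little power with so few libraries, so its result does not decide whether the shift holds. Fry, which tests against no change and not against other genes, gave adjusted p = 0.980 and 0.733. Of 37 members 1 was called lower over all genes (Sostdc1), and adjusted over the list alone 6 were lower and 1 higher. The lower ones were Sostdc1, the secreted antagonists Wif1 (-0.90) and Sfrp1 (-0.91), the receptors Fzd2 (-0.80) and Fzd7 (-0.81), and Tcf7l2 (-0.60); the higher one was the ligand Wnt4 (0.52). Sfrp1 stood at -1.48 without the replicate 1 library labelled cKO and at -0.35 without that of replicate 2. Fzd7 stood at -0.49 without the replicate 1 control and -0.51 without the replicate 2 library labelled cKO, and Wnt4 at 0.29 without the replicate 1 library labelled cKO and 0.28 without the replicate 2 control. Genes of HFSC identity were lower as a group by camera at its preset correlation (adjusted p = 0.0378 and 0.0155), but again not with an estimated correlation (adjusted p = 0.824 and 0.811). Fry, against no change, gave adjusted p = 0.980 and 0.733. Of 32 members 1 was called lower (Lhx2), and adjusted over the list alone 8 were lower and 2 higher. Besides Lhx2 the lower ones were Sfrp1, Tbx1 (-0.72), Ltbp2 (-0.56), Cd34, Tcf7l2, Nfatc1 and Alcam (-0.49), and the higher ones were the matrix protein Tnc (1.197) and the surface protein Cd200 (0.62). Both lists share Sfrp1, Tcf7l1, Tcf7l2, Lgr5 and Dkk3. Tnc stood at 0.54 without the replicate 2 control and 1.85 without the replicate 1 control, and Tbx1 at -0.43 without the replicate 1 library labelled cKO. Without the replicate 1 control Nfatc1 turned to 0.37, Alcam to 0.31 and Tcf7l2 to 0.12, and without the replicate 2 library labelled cKO to 0.25, 0.18 and 0.04. These values carry part of the difference between replicates, and Nfatc1 was lower within both pairs (-0.70 and -0.46). Cd200 stood at 0.27 and Ltbp2 at -0.33 without the replicate 1 control. Neither list call held without the replicate 2 library labelled cKO (0.898 and 0.592) or without the replicate 1 control (0.888 and 0.244), where the direction of HFSC identity turned up in both cases. The HFSC identity call without the block also ended at a pseudocount of 0.1 (0.0773) and with no filter (0.0778). The HFSC identity median was -0.34 in the male pair and 0.02 in the female pair, while 16 of the 32 members were lower and 6 higher in both pairs. The WNT signalling median was -0.27 and -0.10.

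Genes of wounded and inflamed epidermis were higher as a group in the libraries labelled cKO by camera at its preset correlation (adjusted p = 0.000135 without the block and 0.0144 with it), but not with an estimated correlation (adjusted p = 0.824 and 0.811), which has little power here. Fry, which tests against no change and not against other genes, gave adjusted p = 0.980 and 0.733. Of 25 members 2 were called higher over all genes (Stfa3 and Ccl27a), and adjusted over the list alone 5 were higher and 0 lower: Stfa3, Ccl27a, the chemokines Cxcl10 (1.31) and Ccl2 (1.12), and the stress keratin Krt17 (0.70). The list median was 0.04 in the male and 0.32 in the female pair, well below the mean of 0.44 over its members, which Stfa3 raised. Without the replicate 2 library labelled cKO the direction turned down (adjusted p = 0.592), and without the replicate 1 control the call was lost (0.586), as it was at a mean FPKM of at least 5 (0.0688 without the block and 0.323 with it). Krt17 stood at 0.08 without the replicate 1 control and -0.06 without the replicate 2 library labelled cKO. Smooth-muscle genes stood high in the replicate 2 library labelled cKO alone: Acta2 was at 35.8 FPKM there and between 2.02 and 2.81 in the others, and Des and Actg2 at 5.01 and 4.36 FPKM and listed at 0 in the others.

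A further 4 lists were past the threshold in at least one of the fits without and with the block by camera at its preset correlation, and each had adjusted p = 0.824 and 0.811 with an estimated correlation. Immediate early and heat shock genes, which cell dissociation induces, had a median of 0.51 in the male pair and -0.17 in the female pair (0 of 31 called, and 0 adjusted over the list alone; camera adjusted p = 0.0111 and 0.0169 without and with the block, 0.824 and 0.811 with an estimated correlation, 0.421 and 0.516 with quantile normalization, and 0.0596 with the block and the span trend removed). Myc, for example, gave 1.06 and -0.02. Epidermal differentiation genes had medians of 0.02 and -0.56 (0 of 32 called over all genes; adjusted over the list alone Flg, Lor, Klk7 and Alox12b lower and Sprr1b higher; adjusted p = 0.0613 and 0.0148, and 0.824 and 0.811 with an estimated correlation). Alox12b stood at -0.18 and Flg at -0.44 without the replicate 2 control, where Lor turned to 0.92 and Klk7 to 0.44, as they did without the replicate 1 library labelled cKO (0.79 and 0.24). Leukocyte markers, genes of a cell type that the sort should exclude, had medians of 0.02 and -0.60 (0 of 15 called, and 0 adjusted over the list alone; adjusted p = 0.0330 and 0.0409, 0.824 and 0.811 with an estimated correlation, 0.143 and 0.224 at a mean FPKM of at least 5, 0.0999 and 0.123 with no filter, and with the block 0.0626 at a pseudocount of 0.1 and 0.0942 with quantile normalization), with H2-Ab1 at 17.8 and 30.5 FPKM in the libraries labelled cKO and 20.4 and 57.7 in the controls. Proliferation genes had medians of 0.01 and 0.17 (0 of 32 called, and 0 adjusted over the list alone). Their camera adjusted p was 0.0356 and 0.0827, and 0.824 and 0.811 with an estimated correlation. With no filter and no block it was 0.170, and the list was past the threshold in 10 of 28 alternatives. Without the replicate 1 library labelled cKO the immediate early list turned down (median -0.31) and the leukocyte list up (0.07). Without the replicate 2 control the leukocyte list turned up (0.35) and the immediate early call was lost (0.10). Without the replicate 1 control the medians of these 2 lists were 0.32 (immediate early) and -0.96 (leukocyte). They were 0.71 and -0.49 without the replicate 2 library labelled cKO. At the main settings the epidermal list was called with the block and not without it. Without the block it was called lower at a mean FPKM of at least 5 (camera adjusted p = 0.0120) and with quantile normalization (0.000135). Its median was -0.07 without the replicate 1 library labelled cKO and 0.24 without the replicate 2 control. It was -0.65 without the replicate 1 control and -0.42 without the replicate 2 library labelled cKO. The proliferation call was lost without any one of the 4 libraries.

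Signalling lists besides WNT, and the matrix list, were not past the threshold with all 4 libraries. Of 44 genes of activin, TGF-beta and BMP signalling 0 were called, and adjusted over the list alone Inhbb, Fstl1 (-0.90), Id4 (-0.71) and Ltbp2 were lower (camera adjusted p = 0.268 and 0.168 without and with the block). Of 46 other secreted niche factors Slit3 was called higher, and adjusted over the list alone the integrin ligand Npnt (-0.84), the guidance cue Sema3e (-0.87) and the matricellular protein Ctgf (-0.73) were lower (0.879 and 0.819). Of 47 genes of extracellular matrix and basement membrane Adamts1 and Thbs2 were called higher and Timp2 lower, and adjusted over the list alone Tnc was also higher and Npnt, Sparc (-0.86) and Efemp2 (-0.58) lower (0.541 and 0.554). With 1 library left out and no block, the activin list was lower without the replicate 1 library labelled cKO (adjusted p = 0.000709) and without the replicate 2 control (0.000647) and higher without the replicate 2 library labelled cKO (0.0265). The matrix list was higher without the replicate 1 control (0.0005) and without the replicate 2 library labelled cKO (0.00248). Inhbb stood at -0.47 without the replicate 1 control and -0.59 without the replicate 2 library labelled cKO, where Id4 stood at -0.43, Npnt at -0.55, Sema3e at -0.18 and Ctgf at -0.37. Without the replicate 1 control Sema3e stood at -0.30 and Ctgf at -0.31.

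The remaining lists were not past the threshold with all 4 libraries either. Sebocyte and upper follicle genes (23 tested) had camera adjusted p of 0.541 and 0.649 without and with the block, and hair lineage genes (15 tested) 0.0917 and 0.173, with Dlx3 lower by the test adjusted over the list alone (-0.80). For cell-cycle inhibitors and apoptosis genes (25 tested) the values were 0.0671 and 0.168; adjusted over the list alone Gadd45a (0.77) was higher and Bcl2l1 (-0.57) and Cdkn1b (-0.51) lower. Cell adhesion, integrin and cytoskeleton genes (31 tested) gave 0.808 and 0.548, with a median of -0.07, a mean of 0.09 and a test direction that was up without and down with the block. The SOX family (6 tested) gave 0.311 and 0.556, and only Sox4 passed adjusted over the list alone. Dermal fibroblast and papilla markers (6 tested) gave 0.541 and 0.548, with Sparc lower and Col1a2 (0.68) higher adjusted over the list alone. Adipocyte, muscle, erythroid and Schwann markers (6 tested) gave 0.808 and 0.956, with a mean of 0.12 and a direction that was down with the block. Y-linked genes and Xist (5 tested) gave 0.959 and 0.556. With 1 library left out and no block, the adhesion list was higher without the replicate 1 control (adjusted p = 0.000224) and without the replicate 2 library labelled cKO (0.00248) and lower without the replicate 2 control (0.0228). The sebocyte list was lower without the replicate 1 library labelled cKO (0.00172) and higher without that of replicate 2 (0.000362). The Y-linked list was past the threshold without any one of the 4 libraries, lower without the replicate 1 library labelled cKO or the replicate 2 control and higher without the others (4.16e-05 to 0.00698). The adipocyte list was higher with no filter (0.0195). Without the replicate 2 control Bcl2l1 stood at -0.32 and Col1a2 at 0.22, without the replicate 1 library labelled cKO Col1a2 stood at 0.36, and without the replicate 2 library labelled cKO Dlx3 stood at -0.53. Melanocyte markers (Gpnmb at -0.36 and Mitf at 0.02) and endothelial and mural markers (Cspg4 at -0.34, Eng at -0.11 and Egfl7 at 0.09) had too few tested members for the set test.

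**Figure D3:**
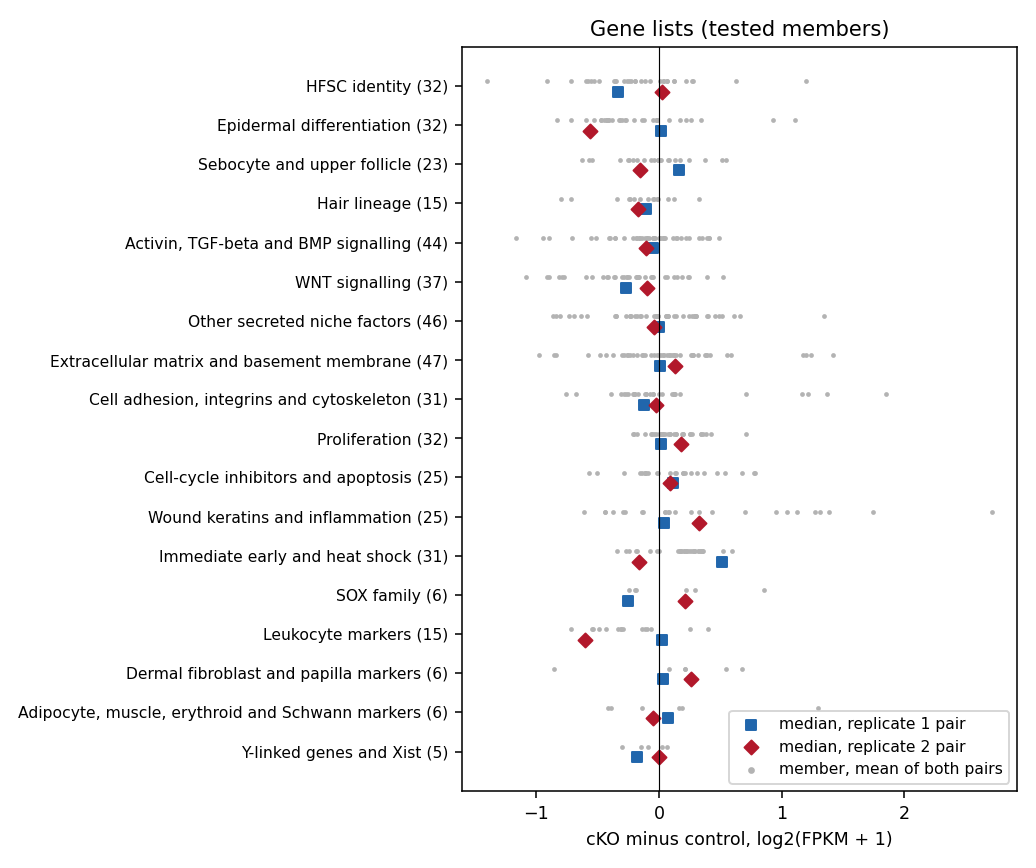
For each list with at least 5 tested members (number in brackets), squares and diamonds give the median log2(FPKM + 1) difference of libraries labelled cKO from controls in the male and the female pair, and grey points the members' mean over both pairs. The symbols of the immediate early, epidermal differentiation and leukocyte lists lie far apart, at 0.51 and -0.17, 0.02 and -0.56, and 0.02 and -0.60.

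The 2 HFSC ChIP lists were compared to find the SOX9 sites seen in both. Of 8181 peaks in list 1, 2047 (25.02%, 95% interval 24.09 to 25.97) overlapped a peak of list 2, and 2049 of the 2989 peaks of list 2 (68.6%) overlapped one of list 1. Circular shifts of a list gave a median of 14 and at most 118 overlaps, so that the overlap lay far above chance (p = 0.000999 by permutation, the smallest that 1000 shifts can give). Peaks in both lists were wider in list 1 than the others (median 739 against 584 bp). Such peaks lay by genes of the basal layer and the bulge: one at 101543699 to 101544862 on chromosome 15, 377 bp from Krt5, one 935 bp from Krt14, one 449 bp from Krt15, and one inside the Lgr5 locus (chromosome 10, 114987149 to 114987820). Nfatc1 had 2 and Lhx2 3 within 10 kb. Whether a peak lies in an exon, intron or promoter was not determined, since the loci carry no strand or exons. With only the wider 50% of each list, 864 peaks were shared.

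SOX9 peaks of HFSCs were set against those of IFE cells, the epidermal cells outside the follicle. Of the 2047 peaks in both HFSC lists, 1248 (60.97%, 95% interval 58.8 to 63.1) overlapped an IFE peak and 799 did not. Peaks by Krt5, Krt14, Krt15 and Nfatc1 were among those also in the IFE list, whereas the peak in Lgr5 and 2 of the 3 by Lhx2 were absent from it. Of the peaks in a single HFSC list, 18.3% of those of list 1 and 49.6% of those of list 2 overlapped an IFE peak; taking either list whole gave 29.0% and 57.6%. Of the 5209 IFE peaks, 2352 (45.2%) were in neither HFSC list. There is 1 IFE library, so that a difference between cell types cannot be told from one between libraries. Expression was not measured in IFE cells, so whether their peaks are SOX9 sites or background of the antibody is not shown.

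Where the peaks lie differed with their presence in the IFE list. Among peaks in both HFSC lists, those also in the IFE list lay within 1 kb of the edge of a gene locus in 45.7% of cases (95% interval 42.9 to 48.5) and those absent from it in 18.3% (15.7 to 21.1), against a median of 5.13% after circular shifts. More than 10 kb from any locus were 13.1% and 30.3%. The 2 HFSC lists themselves differed as well: 20.9% of all peaks of list 1 and 47.1% of list 2 lay within 1 kb of an edge, against 45.4% of the IFE list. The share at an edge thus also differs between libraries of one cell type. For the widest peaks, the nearest locus was sought only among genes with a mean FPKM of at least 1, so other loci can lie closer. The widest peaks in both HFSC lists and absent from the IFE list lay inside the loci of Ablim3 (chromosome 18, 62017439 to 62019385), Slc7a6, Megf6, Eif4enif1 and Aig1, and nearest to Zfp148, Trim2 and Pvrl1 at 58788, 18458 and 181920 bp. The widest in all 3 lists lay at Pisd-ps1 (chromosome 11, 3030630 to 3047407), Eif4enif1, AY036118 (chromosome 17, 39979726 to 39986066) and 72849 bp from Irf2bp2. Peaks 6341 to 16778 bp wide at the first 3 of these are far wider than the list median. The Eif4enif1 peak absent from the IFE list (chromosome 11, 3047415 to 3048963) begins right beside the end of the Pisd-ps1 peak. It may thus be part of the same region and is an uncertain HFSC-only site.

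**Figure D4:**
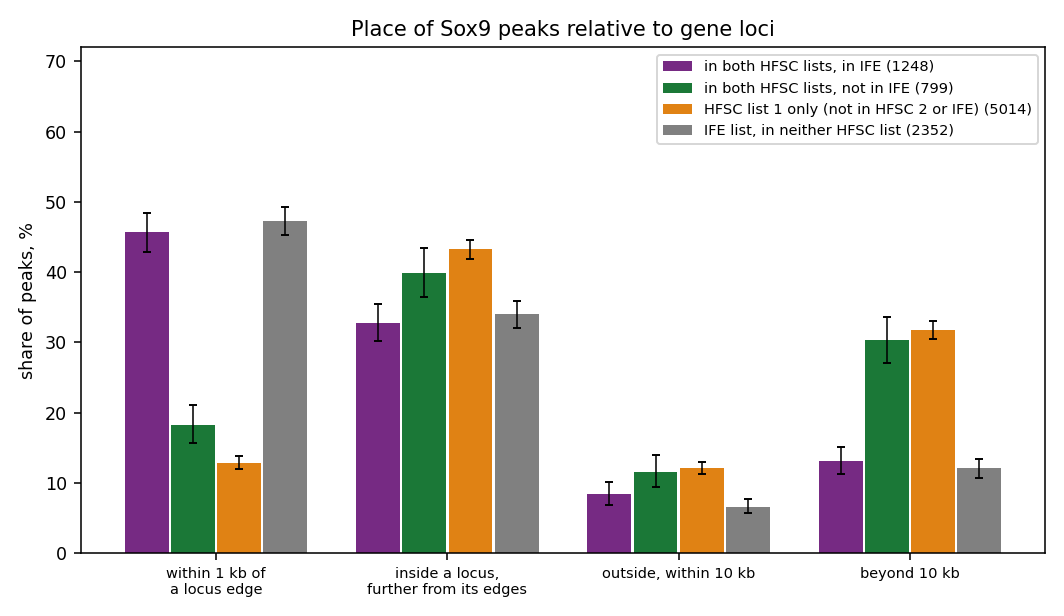
Bars give the share of SOX9 peaks, in %, by place relative to the gene loci of the expression table, with exact 95% intervals, for 4 sets of peaks (numbers in brackets). Peaks near a locus edge make up 45.7% of those in both HFSC lists and the IFE list, and 18.3% of those in both HFSC lists but not the IFE list.

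Peaks and expression were joined to ask which genes changed in the libraries labelled cKO lie by a SOX9 peak. Genes lower in these libraries had a peak more often than other genes: 13 of the 26 called with the replicate block (50%, 95% interval 29.9 to 70.1) lay within 10 kb of a peak in both HFSC lists, against 15.5% of the other tested genes. They were Lhx2, S100a4, Sulf2, Timp2, Mmp11, Wfdc3, Thsd1, Phyhip, Fam132a, 2310057J16Rik, Gm16314 and the small RNAs Snord45b and Mir23a. Lhx2 (chromosome 2, 38194800 to 38225253) had 3 peaks, one inside the locus at 38224006 to 38224854 that is also in the IFE list, and 2 beyond it at 38232539 to 38233161 and 38234514 to 38235051 that are not. Of the 15 genes called higher, Errfi1, Ccl27a and Slit3 had a peak, with 3 for Slit3 at 35121254 to 35121950, 35130991 to 35131811 and 35500488 to 35501502 on chromosome 11. Stfa3, Myoc, Grik1 and Fzd9 had none, and neither did Sostdc1 within 10 kb.

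The test of called genes had been set for the fit without the block, which called no gene. After that was seen it was moved to the blocked calls, which end in some other settings. In these calls the excess among lower genes was larger than in matched draws. The odds ratio was 5.44 (95% interval 2.32 to 12.7; Fisher's exact test, two-sided p = 4.38e-05, adjusted p = 0.000175 over 4 sets), and genes matched on locus length and mean FPKM gave a median of 4 with a peak (p = 2e-04, the smallest that 10000 draws can give). For higher genes it was 1.35 (95% interval 0.245 to 5.02; Fisher's exact p = 0.718, adjusted p = 0.958). Of genes 2-fold lower in both pairs 14 of 40 had a peak (odds ratio 2.93, exact p = 0.00315, adjusted p = 0.0063; 1.86, exact p = 0.135 with peaks inside the locus, and 1.88, exact p = 0.063 with HFSC list 2 alone) and of those 2-fold higher 4 of 28 (odds ratio 0.902, exact p = 1). Peaks absent from the IFE list lay by 10 of the 26 lower genes against 5.27% of others (odds ratio 11.2, exact p = 4.23e-07), and peaks also in the IFE list by 4 of 26 (1.38, exact p = 0.536). Taking all peaks of list 1 or of list 2 gave odds ratios of 4.20 and 3.13 for lower genes, and peaks inside the locus alone 2.75 (exact p = 0.0281).

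Across all 2255 tested genes with such a peak, the median log2 change was -0.027 against -0.0017 in the other genes, and camera found no shift of the set (p = 0.291 without the block and 0.188 with it, and p = 0.607 with the block and an estimated correlation). Of the matched draws 95% had medians between -0.013 and 0.0064, so that the small difference lay outside their range (p = 2e-04 by permutation of matched draws, the smallest that 10000 draws can give). The same comparison gave -0.025 for genes by any IFE peak (matched median -0.0047) and -0.034 for genes by IFE peaks in neither HFSC list (matched median -0.012), also at p = 2e-04 by permutation of matched draws, so that the shift was not limited to genes by HFSC peaks. Some fixed lists lay by peaks more often than matched genes did. Immediate early and heat shock genes had a peak in 16 of 31 cases (matched median 4, adjusted p = 9e-04 by permutation of matched draws), among them Jun, Junb, Fosl2 and Atf3, and WNT signalling genes in 17 of 37 (matched median 6, adjusted p = 9e-04), among them Wnt4, Wnt7b, Wnt10a, Fzd2, Lgr4 and Tcf7l2. HFSC identity genes had one in 17 of 32 cases (matched median 8, adjusted p = 0.0054) and adhesion and integrin genes in 14 of 31 (matched median 7, adjusted p = 0.0247), including Itga3, Itgb4, Cdh1, Cdh3 and Dsp. Epidermal differentiation genes had one in 3 of 32 (matched median 4, adjusted p = 0.951). These counts took peaks in both HFSC lists, whether or not they are in the IFE list. The peaks by Wnt4, Wnt7b and Wnt10a are also in it, and those by Fzd2, Lgr4 and Tcf7l2 are not. The draws match mean FPKM in 5 bins only. Immediate early genes had a median FPKM of 130 to 250 per library, against 11.2 to 12.7 over all tested genes. They may thus stand above their draws.

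**Figure D5:**
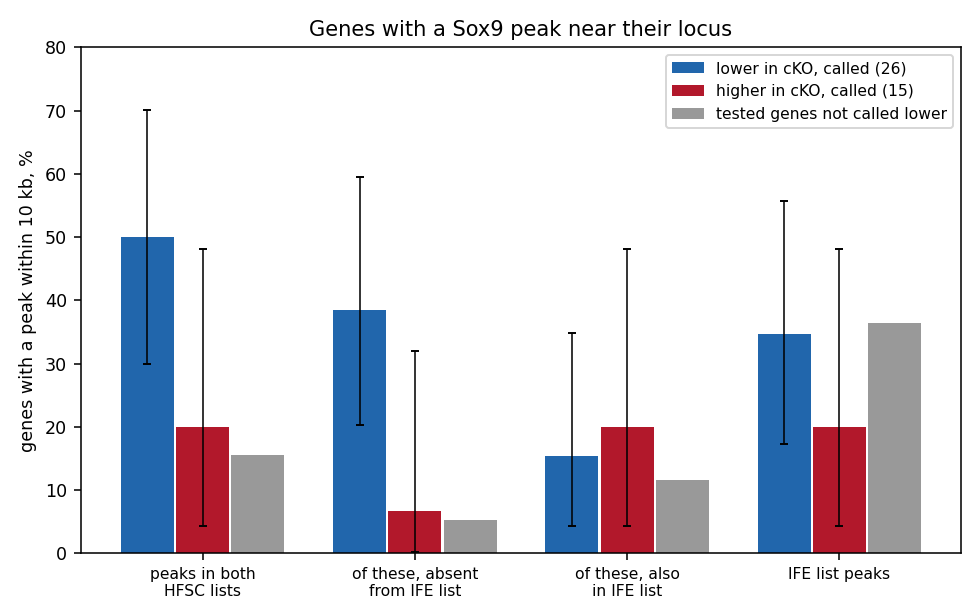
Bars give the percentage of genes with a SOX9 peak within 10 kb, for genes called lower (26) or higher (15) in the libraries labelled cKO with the replicate block, with exact 95% intervals, and for tested genes not called lower. For peaks in both HFSC lists the lower genes stand at 50% against 15.5%, and for IFE list peaks at 34.6% against 36.3%.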

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

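In this part the tests of sex, of a label swap, of the recombined allele and of transcription past Sox9 were chosen only after the result was seen; the test of locus span was not.

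Some effects pointed in opposite directions in the male and the female pair. Sox9 differed by -0.21 (log2) between the library labelled cKO and the control in the male pair and by 0.78 in the female pair, and Col1a1, a fibroblast collagen, by -1.07 and 2.15; with 1 library per genotype and sex neither difference between pairs was tested. The medians of the HFSC identity list were -0.34 and 0.023, those of epidermal differentiation 0.018 and -0.56, those of immediate early and heat shock genes 0.51 and -0.17, and those of leukocyte markers 0.021 and -0.60. These differences between lists' medians have no test that takes libraries as replicates either. Sex goes with age and replicate number here, so that the difference cannot be assigned to any of them.

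Sox9 FPKM was not consistently lower in the libraries labelled cKO. A swap of the genotype labels in 1 pair is argued against, since the pair differences then should run opposite across genes and they correlated at 0.217; a swap in both pairs was not tested. A candidate explanation is that RNA of the recombined allele still counts toward the gene, and the whole-gene change of 0.28 leaves this open because no value per exon is held. Transcription running on past the recombined allele may account for Gm11681 and 4933434M16Rik: they are 2 of the 3 other loci within 50 kb, both on the higher-coordinate side, and among 37298 loci only 10 met the same marks (at least 0.5 FPKM in both libraries labelled cKO and at most 0.05 in both controls; exact hypergeometric p = 1.94e-07, with marks chosen after the values were seen and neighbouring loci not independent). That Sox9 is transcribed toward higher coordinates is textbook knowledge, and a biological effect of losing SOX9 on these loci was not tested.

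The replicate 2 libraries differed from the replicate 1 libraries in both genotypes, with 1959 of 14455 genes at least 2-fold apart. Of these genes 5.92% lie on X or Y, against 4.45% of all tested genes; sex stays open, since it also acts on genes of other chromosomes and goes with the replicate number. A gene length bias between library preparations may account for part: the replicate difference fell with locus span (Spearman rho = -0.394), ribosomal protein genes and their copies had a median of 1.44, and once a trend on span was taken out 47.12% of those 1959 genes were still 2-fold apart, which lies between the marks set for and against it. In all, 1343 genes were 2-fold apart once the trend was out, and only 923 of them were among the 1959. Age and the days of RU486 treatment go with the replicate number and stay open, untested.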

How the results depend on the processing

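In this part the tests that join the replicate block with another setting, those on the wider 50% of peaks and the count over 76 genes were chosen only after the result was seen. An upper 50% by peak score was not run, since the lists hold no score, and the blocked fit without 1 library could not be tested, since no residual degrees of freedom remain; without the block the lone library is assumed to vary like the other group. The cause of a changed result was not tested unless named here.

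Genes changed: limma called 0 without the block and 41 with the replicate block. With the block and other settings it called 33 (pseudocount 0.1), 78 (pseudocount 5), 53 (mean FPKM of at least 5), 52 (median scaling), 3 (quantile normalization), 96 (threshold 0.1), 64 (no gene listed at 0) and 56 (Ccl27 copies once and small RNAs left out), and 0 without the filter, without the trend, with the span trend removed and with 1 pair flipped (321 genes at p under 0.05). Without 1 library and without the block there were 2 to 41 calls, and the change of Sox9 lay between -0.13 and 0.69. Genes 2-fold in both pairs numbered 135 (pseudocount 0.1), 24 (pseudocount 5), 43 (mean FPKM of at least 5) and 269 (1.5-fold). Camera with an estimated correlation and fry each called 0 lists, without and with the replicate block. The former has little power with so few residual degrees of freedom, and fry tests against no change.

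Peaks: the wider 50% of each list shared 864 peaks, of which 51.16% lay in the IFE list; with an overlap of at least 50% of both peaks it was 54.79%, and from 28.95% to 57.61% with 1 HFSC list. The odds ratio of a peak by higher genes called with the replicate block, 1.35, became 0.438 with IFE peaks, 0.984 with no gene listed at 0, and 0.677 to 0.781 with 1 HFSC list. In place of the called genes, those 2-fold higher in both pairs gave 0.902. For lower genes it was 0.928 with IFE peaks.

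Of 2604 values of 112 genes fixed by the naming rule, Sox9 apart, in 24 settings, 2319 had the sign and the side of the threshold of the fit without the block, whatever their size. Another 242 passed the threshold where that fit did not, and 43 reversed in sign, in 25 genes. Of 76 genes called with the block or past the test over a list alone, 6 turned in sign and 37 moved over 1.5 times without 1 library. Xist was -0.16 at pseudocount 0.1 and Krt5 -0.040 with quantile normalization, both also with the replicate block. Without 1 library the ranges that crossed 0 were Myc -0.16 to 1.199, Hsph1 -0.22 to 0.92, Mitf -0.80 to 0.83, Cd3g -1.02 to 0.034, H2-Ab1 -1.27 to 0.18, Cspg4 -0.98 to 0.31, Eng -0.56 to 0.33, Egfl7 -0.36 to 0.55, Col1a1 -0.75 to 1.83, Vim -0.14 to 0.56, Hba-a1 -1.21 to 0.38, Eif2s3y -3.21 to 2.60, Kdm5d -1.65 to 1.36, Ddx3y -2.23 to 2.05, Xist -2.99 to 3.13, Nfatc1 -1.53 to 0.37, Tcf7l1 -1.12 to 0.56, Krt15 -0.13 to 0.20, Lgr5 -1.07 to 0.55, Krt10 -0.90 to 0.30, Ivl -1.01 to 0.062, Scd1 -0.60 to 0.94, Krt14 -0.44 to 0.30 and Mki67 -0.30 to 0.33. List medians ranged from -0.46 to 0.20 (HFSC identity), -0.65 to 0.24 (epidermal differentiation), -0.064 to 0.59 (wound), -0.31 to 0.71 (immediate early), -0.96 to 0.35 (leukocyte), -0.47 to 0.036 (WNT signalling) and -0.028 to 0.17 (proliferation). Leaving out 1 library without the block unbalances the replicates and the sexes, so part of the difference between replicates enters every such range. Y-linked genes and Xist cross 0 by construction for this reason. Nfatc1 (-0.70 and -0.46) and Lgr5 (-0.32 and -0.20) were lower within both pairs, although their ranges cross 0.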

Other observations

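In this part the tests of peaks near locus edges, of HFSCs in the IFE sort and of lower calls by HFSC-only peaks were chosen only after the result was seen; the other tests were not.

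Some genes moved at least 2-fold in both pairs without passing limma with the block. Apart from Cxcl10, those given here were picked by no fixed rule, after the values were seen. Higher in both libraries labelled cKO were Epas1, a hypoxia-inducible factor (log2 change 1.26), Adm, which encodes the vasodilator peptide adrenomedullin (1.12), the chemokine Cxcl10 (1.31), Guca2a (1.36), Nptx1 (1.23) and the cornified envelope gene Sprr2a2 (1.42). Lower in both were Scrg1 (-1.87), Msrb3, a methionine sulfoxide reductase (-1.57), Spon2, a matrix protein (-1.12), and Mir10b (-2.11), a small RNA that this library type captures poorly. Mir140 (-1.60, limma with the replicate block, adjusted p = 0.0904) is listed at the locus of its host gene Wwp2 (-1.57), so that these values are not independent; this pair was singled out after the values were seen.

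Most peaks of both HFSC lists overlap an IFE peak. Regions near locus edges that gather peaks in any cell are a candidate explanation: peaks also in the IFE list lay at an edge more often in each of the 4 width quartiles, by at least 24.07 percentage points. HFSCs in the IFE sort, which the CD34 gate should remove, would share all peaks alike, and edge peaks exceeded peaks beyond 10 kb by at least 33.8 points in each quartile (79.6% against 40.4% in all). This passes the mark written for excluding such cells, but the explanation is left open because width is not strength and the lists hold no strength. SOX9 binding the same sites in both cell types is the biological alternative, and it was not tested apart from these. Expression was measured in HFSCs only, so whether the IFE cells hold SOX9 is not shown here. Peaks shared with the IFE list may therefore be background of the antibody, which these lists cannot tell from binding.

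Secreted factors were the stated interest of the series. A hypothesis written in advance was that genes of the activin, WNT and other secreted lists lie by HFSC peaks more often than like genes, and 32 of 127 did (25.2% against 15.5% of other genes; matched median 23, one-sided permutation p = 0.0243). The WNT list carried this, with 17 of 37 members (matched median 6), whereas the activin list had 6 of 44 (matched median 8) and the other secreted factors 9 of 46 (matched median 9). These counts took peaks in both HFSC lists, whether or not they are in the IFE list. All such peaks by Wnt4, Wnt5b, Wnt7b, Wnt10a, Wnt10b, Fzd6, Fzd10, Lrp5, Tcf7, Znrf3 and Rnf43 are also in the IFE list. Fzd2, Lrp6, Dkk3, Lgr4, Lgr5 and Tcf7l2 have a peak that is not. Over the 3 lists, members with a peak had a median change of -0.082 and those without one -0.096, a difference that was not tested. Of the 32, 15 were lower and 6 higher in both pairs.

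A further hypothesis written in advance was that genes by HFSC-only peaks are lower in the libraries labelled cKO than genes by peaks shared with IFE. The medians were -0.044 and -0.023, a difference of -0.0217 (permutation p = 0.0728), which leaves it open. Of draws of shared genes matched to the HFSC-only genes, 95% had medians between -0.036 and -0.0060, above that of the HFSC-only genes. Among genes called lower with the block, 9 of 572 genes by HFSC-only peaks stood against 3 of 1485 by shared peaks (odds ratio 7.89, Fisher's exact p = 0.000893). The genes include S100a4, Sulf2 and Timp2, the calls end in some other settings, and whether SOX9 acts on them through these sites was not tested.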
